A study of Homo sapiens with 15 samples.

How the data were processed

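Cells of MCF-7, an established human breast cancer line that carries the estrogen receptor, were seeded at 20000 per well in medium with 10% serum. Per the labels' protocols they were kept for 24 h in medium stripped of steroids and then exposed for 48 h, in 3 independent experiments. The labels give 5 groups of 3 libraries: Negative, Estradiol, BPA (bisphenol A), BPAF (bisphenol AF) and Glyphosate. The doses and the vehicle of the Negative group are not given in the sources used here. RNA from up to 3 wells was combined for each library. Libraries were made from 100 ng of total RNA after removal of ribosomal RNA, with a kit that keeps the strand and 15 cycles of PCR, and were read as pairs of 100 bases on 2 lanes of an Illumina instrument, per the labels' protocols.

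The deposited table holds log2 values for 58051 Ensembl gene identifiers in 15 columns, 1 per library. The submitters' processing notes name bcl2fastq, FastQC, cutadapt, HISAT2, HISAT and SAMtools and the build hg38, with no versions or roles. The counting tool, its annotation and its strand setting are not given in the sources used here. From the values, each deposited log2 value is the log2 of a count plus 0.5, divided by the gene's summed exon length in kilobases and by a library size. Of 15934 genes at the lowest level in all 15 libraries, 97.4% followed exon length within 0.01. Among 306786 values with a recovered count under 200, 94.3% came out whole within 0.1. The library size equalled the recovered total times the normalization factor in the labels times a constant of 0.978 to 0.980. Recovered totals ran from 9.81 M to 27.4 M, and at these depths the added 0.5 draws the fold changes of low genes toward 0. Wells, PCR copies and sequencing pairs are not independent molecules, so recovered counts bound counting error only. Gene names and coordinates are from GENCODE release 29 on GRCh38, which holds 57447 of the identifiers and lacks 604.

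Because the table is on a log2 scale, the comparisons were tested with limma 3.58.1 in R 4.3.3, with group means over all 15 libraries, a variance trend with level and no other term. Genes with a log2 value of at least 0 in at least 3 libraries were kept, which left 18971. P-values were adjusted by the Benjamini-Hochberg method over these genes within each of the 7 comparisons, and a gene was called at an adjusted p below 0.05; every adjusted p of a gene is limma's. Fold changes are differences of mean log2 values, given with limma's standard error, and levels are given as mean ± SD with n = 3. The groups, tests, gene lists and alternative settings were fixed before the data were examined, apart from those named below or in the text as chosen later. Limits of precision come from the number of libraries, from depth and, without a replicate term, from differences between the experiments.

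Gene lists were drawn up from background knowledge: estrogen-induced genes, estrogen-repressed genes, DNA replication, mitosis, replication-dependent histones, ribosome biogenesis, aryl hydrocarbon receptor targets, PXR and CAR targets, NRF2 oxidative stress targets, unfolded protein response, heat shock, p53 targets, interferon-stimulated genes, cholesterol and fatty acid synthesis, hypoxia, immediate early genes, nuclear receptors (with GPER1 and AHR, which are receptors of other classes), luminal epithelial markers, basal epithelial markers, fibroblast and mesenchymal markers, short structured non-coding RNAs and mitochondrially encoded mRNAs. Of these 22 lists, 18 had at least 5 tested members and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera was run again with the correlation estimated for each list, and none of the calls held with it. With the replicate block described below, ribosome biogenesis alone was called at an estimated correlation, in each comparison with Negative. Its p is given beside each call as the adjusted p with an estimated correlation. In 15 of the 126 list tests the median, the mean and the direction of the test differed in sign, and none of those 15 was called. Members adjusted over the list alone were also counted. A few genes belong to more than 1 list.

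Named genes follow a fixed rule. For each comparison it takes the 10 largest rises and the 10 largest falls among called genes whose 3 libraries of the first group all lie beyond the 3 of the second, as 10% of genes do by chance, and whose mean level is above the median, leaving out pseudogenes and genes with names of clones, antisense, intergenic or small RNAs; this filter works on annotated types and name patterns and let RN7SL809P, a copy of the 7SL RNA, through. Where none passed, it takes the 5 smallest p-values. It adds TFF1, PGR, GREB1, PDZK1, CXCL12, MYC, CCND1 and ESR1, and, for each list, the 4 members with the smallest p. Genes named outside this rule were chosen after their values were seen, and the text says so. Of 223 genes in the rule's tables, 103 share exon sequence with another annotated gene and 83 with a gene on the opposite strand. Since the strand setting of the counting is not known, reads of such genes may be divided or merged. The same holds for near-identical copies such as histone genes and RN7SL2.

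The labels give each group the replicate numbers 1, 2 and 3, and whether a number marks an experiment was checked on the data. Deviations from the group mean correlated between libraries of the same number in all 30 pairs, at 0.105 to 0.406 with a median of 0.219. Between libraries of different numbers the median was -0.150 and the highest 0.0799, and 15 of 15 libraries correlated best with their own number. The numbers were therefore treated as pairing the libraries. The planned fit has no replicate term, and the fit with a replicate block is given beside a result where it changes the call or moves a count by over 1.5 times; for Estradiol against Negative the block raised the count from 2696 to 5672. No pair of libraries in a group agreed within counting error: the chi-square per gene was 11.6 to 64.0 over 13416 genes.

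The scripts were tested on simulated negative binomial counts with the levels, spread within groups and depths of these libraries. The simulated libraries were drawn independently, without the deviations that libraries of the same number share. The shares recovered and the false calls therefore hold for libraries without such pairing. At true folds of 1.5, 2 and 4, the test recovered 27.3%, 41.3% and 75.8% of changed genes for Estradiol against Negative (18327 genes, 4 false among 98 calls). For BPA against Negative it recovered 24.6%, 50.0% and 89.2% (18354 genes, 5 false among 112). For BPAF against Negative it recovered 25.8%, 47.6% and 80.0% (18277 genes, 3 false among 102), and for Glyphosate against Negative 22.7%, 40.0% and 73.4% (18341 genes, 8 false among 96). For BPAF against BPA the shares were 19.0%, 44.4% and 75.0% (18300 genes, 6 false among 94). A simulated list of 30 genes changed 1.5-fold was called and 0 of 20 unchanged lists were. The simulated genes were drawn independently of each other. This run therefore does not test the p-values of lists whose members are correlated.

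The alternatives tried were a replicate block, a fit on the 6 libraries of a comparison, no filter (42117 genes), a stricter filter of 2 in place of 0 (10353 genes), an added count of 5 in place of 0.5, median-centred and quantile scaling, limma without trend, a fold minimum of 1.5, and each library left out in turn. Added after the data were seen were limma voom on the recovered counts of 18882 genes with and without the block, all replicate 3 libraries left out, and BPAF replicate 2 left out with the block. Correlations of fold changes were set beside 100 simulations of unchanged groups against the same Negative libraries, and those of the alternatives beside 100 more for each. Shared calls and same signs were set beside 100 simulations of the same kind. Nuclear copies of mitochondrial genes were compared with blastn 2.17.0. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.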

Results

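RNA was measured by sequencing in MCF-7 cells, an established human breast cancer line that carries the estrogen receptor and grows with estrogens. The series asks for endocrine effects of foreign compounds. Cells deprived of steroids were exposed for 48 h to estradiol, the main natural estrogen, to bisphenol A (BPA) or bisphenol AF (BPAF), which are used in plastics, or to glyphosate, a herbicide, and the Negative group stood as control. Each of the 5 groups had 3 libraries, numbered 1 to 3, and per the labels these came from 3 independent experiments. No doses are given, so sizes of response cannot be set against dose. The deposited log2 values were tested for 18971 genes.

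Library totals recovered from the values were 9.81 M for Estradiol replicate 2, 27.4 M for Negative replicate 3 and 13.8 to 18.0 M for the other libraries. RN7SL2, the RNA of the signal recognition particle, took 13.7% to 25.7% of the summed linear values. The luminal keratin genes KRT8, KRT18 and KRT19 were among the most abundant mRNAs, with mean log2 values of 9.62, 9.42 and 9.54. All 37 genes of the mitochondrial genome were at zero in every library, so the list of mitochondrially encoded mRNAs could not be tested. The first principal component held 23.4% of the variance and the second 15.2%. Replicate 3 libraries of all groups lay lower on the first component than the other libraries of their group, and BPAF replicate 2 stood apart on the third component, at 54.7. That library held 29353 genes at zero, against 29944 in Estradiol replicate 2, the shallowest library, and 23743 to 28595 in the others. These 2 libraries were highest on the first component, at 47.9 and 57.5. Glyphosate replicate 3 and Negative replicate 3, with 25530 and 23743 genes at zero, were lowest, at -50.8 and -62.3. That component is therefore not told apart from the number of genes detected. Each Negative library had fewer genes at zero than the Estradiol library of its number.

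**Figure D1:**
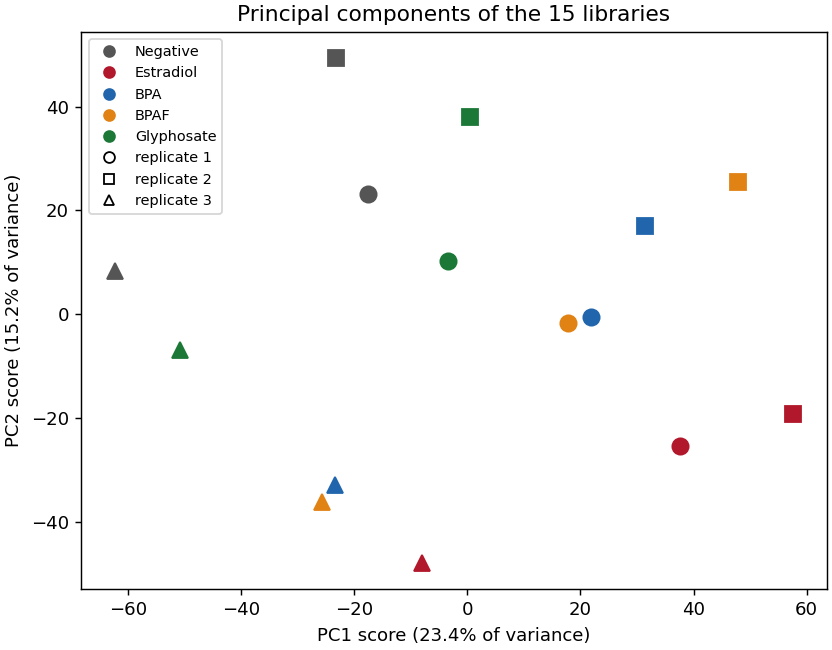
Principal components of the log2 values of 18971 genes, with the first component (23.4% of the variance) on the x axis and the second (15.2%) on the y axis. Each point is 1 library, coloured by group and shaped by replicate, and Estradiol libraries lie lower on the second component than the Negative library of the same number.

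Estradiol against Negative served as the positive control for a response to estrogen. Of 18971 genes, 1333 were higher and 1363 lower with estradiol, 2696 in all, and 894 of these differed at least 2-fold. GREB1, an estrogen-induced cofactor of the estrogen receptor (ENSG00000196208, chromosome 2, 11482341 to 11642788), rose 12.6-fold, with a log2 change of 3.66 ± 0.29, adjusted p = 1.18e-05. Its log2 value was 7.77 ± 0.19 with estradiol and 4.11 ± 0.69 in the Negative group (mean ± SD, n = 3). PGR, the progesterone receptor (ENSG00000082175, chromosome 11, 101029624 to 101130524), rose 12.9-fold (log2 3.69 ± 0.45, adjusted p = 0.000235). TFF1, a secreted trefoil peptide (ENSG00000160182, chromosome 21, 42362282 to 42366594), rose 9.09-fold (log2 3.18 ± 0.54, adjusted p = 0.00181). Other large rises were those of NPY1R, a receptor of neuropeptide Y (3.25), PKIB, an inhibitor of protein kinase A (3.10), AREG, a ligand of the EGF receptor (2.94), ADAMTS9, a secreted protease (2.58), SFXN2 (2.55), the transcription factor MYB (2.37) and RERG, a Ras-like growth inhibitor (2.18). The largest fall of a named gene was that of CLEC3A, a C-type lectin (ENSG00000166509, chromosome 16, 78022515 to 78066761), at log2 -4.52 ± 0.33, adjusted p = 1.02e-05. EPAS1, a hypoxia-inducible transcription factor (ENSG00000116016, chromosome 2, 46293667 to 46386703), fell 12.7-fold to a log2 value of 1.35 ± 0.41 from 5.02 ± 0.26 (adjusted p = 1.14e-05). ALDH1A3 (-3.43) and DHRS3 (-3.09), enzymes of retinoid metabolism, fell too, as did PSCA (-3.38), the adenylate cyclase ADCY5 (-3.36), the epithelial transcription factor GRHL3 (-3.08), the GTPase RND1 (-2.98), AHRR, the repressor of the aryl hydrocarbon receptor (-2.55), and RASD1 (-2.52).

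Of 42 estrogen-induced genes tested, 27 rose with estradiol, 32 adjusted over the list alone, with a median log2 change of 1.11 (adjusted p = 1.45e-19, and adjusted p = 0.0524 with an estimated correlation). PDZK1, a scaffold protein (1.48 ± 0.46, adjusted p = 0.0479), CXCL12, a chemokine (2.63 ± 0.35, adjusted p = 0.000402), and CCND1, cyclin D1 (0.39 ± 0.11, adjusted p = 0.0297), were among them, as were MYBL1 (3.22) and TPD52L1 (1.20). HSPB8, a small heat shock protein of this list, fell (-0.62 ± 0.17, adjusted p = 0.0271), and it was picked out after its value was seen. MYC had a log2 change of 0.42 ± 0.19, adjusted p = 0.169, 0.0366 with the replicate block, and ESR1, the estrogen receptor, -0.03 ± 0.15 (adjusted p = 0.922). Of 16 estrogen-repressed genes, 12 fell, 14 adjusted over the list alone, with a median of -1.01 (adjusted p = 2.08e-08, and adjusted p = 0.0524 with an estimated correlation). These included IL1R1, the receptor of interleukin 1 (-3.16), the growth factor receptor ERBB2 (-1.08), BIK, which promotes apoptosis (-0.94), and MXD4 (-0.56), while PDCD4, picked out after its value was seen, rose (0.75).

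Genes of growth and division rose with estradiol. Of 34 DNA replication genes 29 rose, and 34 adjusted over the list alone, with a median of 0.83, examples being MCM10 (1.31), POLE2 (1.13), GINS1 (1.05) and RFC4 (0.99). Of 32 mitosis genes 30 rose, and 32 adjusted over the list alone, with a median of 1.02, among them TTK (1.18), CCNA2 (1.06), NDC80 (1.02) and TOP2A (0.90). Of 25 replication-dependent histone genes 18 rose, and 24 adjusted over the list alone, with a median of 0.80, as HIST1H3G (1.19) and HIST1H4C (0.95) did. The adjusted p was 1.45e-19 for DNA replication, 1.06e-19 for mitosis and 3.90e-14 for the histones, and each had an adjusted p = 0.178 with an estimated correlation. Of 18 ribosome biogenesis genes 12 rose, 14 adjusted over the list alone, with a median of 0.49 (adjusted p = 1.61e-07, and adjusted p = 0.178 with an estimated correlation), among them UTP20 (0.58), WDR12 (0.65), FBL (0.58) and NPM1 (0.45), while GNL3, picked out after its value was seen, fell (-0.31). Of 10 immediate early genes 5 fell, 6 adjusted over the list alone, with a median of -0.79 (adjusted p = 0.000793, and adjusted p = 0.275 with an estimated correlation): FOSB (-1.65), JUN (-0.94), JUNB (-0.80), IER2 (-0.54) and ATF3 (-1.62), the last picked out after its value was seen.

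Among 21 genes of cholesterol and fatty acid synthesis 19 had values above 0 with estradiol (median 0.43, adjusted p = 0.0102, and adjusted p = 0.654 with an estimated correlation). The desaturase FADS1 rose (0.59), 1 gene also when adjusted over the list alone, against 15 rises and 2 falls with the replicate block. All 14 interferon-stimulated genes had values below 0 (median -0.55, adjusted p = 0.0306, and adjusted p = 0.621 with an estimated correlation), and OAS1 fell (-1.31), the 1 fall adjusted over the list alone as well. Of 6 aryl hydrocarbon receptor targets TIPARP rose (1.18) and AHRR fell (median -1.01, adjusted p = 0.291, 0.0244 with the replicate block and adjusted p = 0.331 with the block and an estimated correlation). Of 5 PXR and CAR targets, genes of drug metabolism and export, ABCC3 fell (-1.55), joined by CYP2A6 (-1.44) when adjusted over the list alone (median -1.24, adjusted p = 0.0755, 0.0198 with the block and adjusted p = 0.106 with the block and an estimated correlation). Of 10 heat shock genes HSPD1 (0.57), HSPA8 (0.46) and HSPB1 (0.75) rose, 4 adjusted over the list alone with HSPE1 (median 0.25, adjusted p = 0.142, 0.0491 with the block and adjusted p = 0.425 with the block and an estimated correlation). Of 11 hypoxia genes EGLN3 (-1.98), NDRG1 (-1.37) and VEGFA (-0.59) fell, 3 also adjusted over the list alone (median -0.26, adjusted p = 0.125, 0.0366 with the block and adjusted p = 0.188 with the block and an estimated correlation).

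The remaining lists did not pass for estradiol, with or without the replicate block, though some members did. In the unfolded protein response (15 genes, adjusted p = 0.772, 0.900 with the block) the chaperones HSP90B1 (0.60) and PDIA4 (0.51) rose, and ATF4 (-0.35), HERPUD1 (-0.39) and ATF3 (-1.62) fell, while 4 rose and 5 fell adjusted over the list alone, with HSPA5, XBP1, CHAC1 and EDEM1 added, named after their values were seen. Of 20 p53 targets (adjusted p = 0.207, 0.208 with the block) SESN2 (-0.61), BBC3 (-0.78) and PLK3 (-0.87) fell, 3 also adjusted over the list alone. TXN, thioredoxin, was the 1 riser of 12 NRF2 oxidative stress targets (0.85; list adjusted p = 0.909, 0.907 with the block). The list named nuclear receptors also holds 2 receptors of other classes, GPER1, a G protein-coupled receptor of the membrane, and AHR, the aryl hydrocarbon receptor, a bHLH-PAS factor. Of its 14 genes (adjusted p = 0.220, 0.134 with the block) PGR, GPER1 (1.20) and RARA (0.74) rose, and RARG (-0.61), AHR (-1.06), NR3C1 (-0.73) and PPARG (-1.17) fell, with VDR added to these falls adjusted over the list alone. RARA, NR3C1, PPARG and VDR were picked out after their values were seen. Of 10 luminal epithelial markers (adjusted p = 0.993, 0.907 with the block) TFAP2C rose (0.74) and ELF3 fell (-1.67). Too few members for a test were measured of the basal markers, where EGFR had -0.88 ± 0.30, adjusted p = 0.0742, 0.00252 with the block, TP63 -1.99 (adjusted p = 0.430, 0.0195 with the block), TRIM29 -0.47 and KRT17 -0.15. The same held for the fibroblast markers COL1A1 (0.97 ± 0.37, adjusted p = 0.101, 0.0167 with the block) and FN1 (-0.93 ± 0.91, adjusted p = 0.559, 1.82e-05 with the block), and for the short structured RNAs RMRP (-0.36), SNORD3A (-0.29), SNORA73B (-0.23) and RN7SL2 (-0.17), of which none passed.

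With the replicate block 5672 genes changed with estradiol, all 2696 among them. The count was 1631 without Negative replicate 2, 1667 without Negative replicate 3, 1652 without Estradiol replicate 1 and 1577 without Estradiol replicate 2. The cholesterol list had an adjusted p = 0.0982 without Estradiol replicate 2 and 0.140 without Negative replicate 3, and the interferon list 0.152 without Estradiol replicate 2 and 0.196 without Negative replicate 1. Of 72 called genes of the naming rule, 15 lost the call without some single library: AREG, ATF4, BBC3, CCND1, FADS1, FOSB, HERPUD1, HSPA8, HSPB1, JUNB, NDRG1, OAS1, PDZK1, PLK3 and RASD1.

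**Figure D2:**
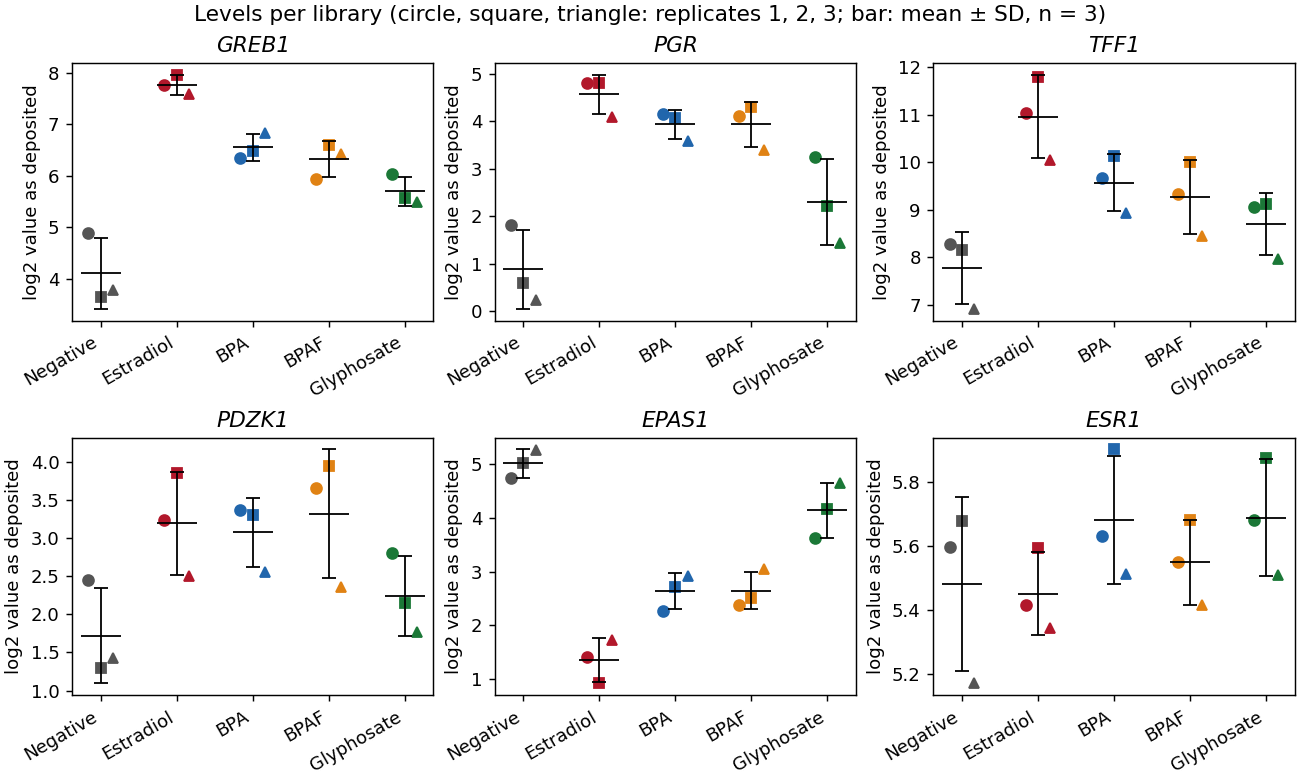
Log2 values (y axis) of GREB1, PGR, TFF1, PDZK1, EPAS1 and ESR1 for the 5 groups on the x axis. Points are libraries, shaped by replicate, and bars the mean ± SD of 3, and for GREB1 the mean was 4.11 in the Negative group and 7.77 with estradiol.

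BPA against Negative asked whether bisphenol A, a compound with estrogen-like activity, alters expression in these cells. BPA raised 296 genes and lowered 280, 576 in all, of which 152 differed at least 2-fold. PGR rose 8.29-fold (log2 3.05 ± 0.45, adjusted p = 0.00476) and GREB1 5.44-fold (log2 2.44 ± 0.29, adjusted p = 0.00193), the latter to a log2 value of 6.55 ± 0.26 from 4.11 ± 0.69. PKIB (2.15), NPY1R (2.15), SFXN2 (2.01), the receptor tyrosine kinase RET (1.95), STC1, a secreted glycoprotein (1.90), MYB (1.81), ADAMTS9 (1.75) and MSMB (1.69) rose as well. CLEC3A fell 5.37-fold (log2 -2.43 ± 0.33, adjusted p = 0.00343) and EPAS1 5.23-fold (log2 -2.39 ± 0.28, adjusted p = 0.00193). ALDH1A3 (-2.31), PSCA (-2.09), DHRS3 (-1.83), NTN4, a netrin of the basement membrane (-1.73), the keratin KRT81 (-1.73), UPK2 (-1.68), GRHL3 (-1.60) and TGFBI, an extracellular matrix protein (-1.56), fell. TFF1 had a log2 change of 1.80 ± 0.54, adjusted p = 0.0912, 5.56e-05 with the replicate block, CXCL12 of 1.37 ± 0.35, adjusted p = 0.0514 (0.00195 with the block) and PDZK1 of 1.35 ± 0.46, adjusted p = 0.135 (0.00774 with the block). MYC (0.36 ± 0.19, adjusted p = 0.353), CCND1 (0.17 ± 0.11, adjusted p = 0.477) and ESR1 (0.20 ± 0.15, adjusted p = 0.550) did not pass.

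Of 42 estrogen-induced genes 13 rose with BPA, 27 adjusted over the list alone and 32 with the replicate block, and 40 had values above 0 (median 0.99, adjusted p = 9.68e-19, and adjusted p = 0.0583 with an estimated correlation). Of 16 estrogen-repressed genes IL1R1 (-2.10) and ERBB2 (-0.71) fell, 7 adjusted over the list alone and 12 with the block (median -0.65, adjusted p = 6.06e-07, and adjusted p = 0.0583 with an estimated correlation). Of 34 DNA replication genes 8 rose, 33 adjusted over the list alone and 34 with the block, with RFC4 at 0.83 and MCM10 at 1.20 (median 0.68, adjusted p = 3.31e-20, and adjusted p = 0.240 with an estimated correlation). Of 32 mitosis genes 6 rose, 28 adjusted over the list alone and 28 with the block, CCNA2 (0.83) and TTK (0.76) among them (median 0.62, adjusted p = 1.74e-16, and adjusted p = 0.277 with an estimated correlation). HIST1H2AB (0.86) and HIST1H3G (0.88) rose of 25 histone genes, 16 adjusted over the list alone and 18 with the block (median 0.56, adjusted p = 8.50e-11, and adjusted p = 0.280 with an estimated correlation). POLR1B, a subunit of RNA polymerase I (0.34), rose of 18 ribosome biogenesis genes, 13 adjusted over the list alone and 12 with the block (median 0.33, adjusted p = 6.06e-07, and adjusted p = 0.229 with an estimated correlation). The 10 immediate early genes were called lower (median -0.61, adjusted p = 0.00109, and adjusted p = 0.294 with an estimated correlation) with 0 members passing limma's test, 3 adjusted over the list alone (JUN, JUNB and IER2) and 6 with the block.

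The other lists were not called for BPA. Cholesterol and fatty acid synthesis had an adjusted p = 0.0722, 0.000146 with the replicate block, where 11 of its 21 genes rose against 0 by limma without it, and adjusted p = 0.230 with the block and an estimated correlation. TIPARP rose (0.66) and AHRR fell (-1.33) among aryl hydrocarbon receptor targets (list adjusted p = 0.506), HSP90B1 rose (0.37) in the unfolded protein response (0.756), and EGLN3 (-1.56) and VEGFA (-0.51) fell among hypoxia genes (0.262). PGR and GPER1 (0.93) rose and PPARG (-1.12) and AHR (-0.83) fell in the list of nuclear receptors, GPER1 and AHR (0.212). No member passed limma's adjusted test among PXR and CAR targets (list adjusted p = 0.218), NRF2 targets (0.808), heat shock genes (0.455), p53 targets (0.104), interferon-stimulated genes (0.10) or luminal markers (0.549). Adjusted over the list alone, ABCC3, HSPD1, XBP1, PDIA4, ATF4, HERPUD1, RARG and NR3C1 passed besides the members just given, XBP1, RARG and NR3C1 being named after their values were seen. With the block 3287 genes changed with BPA, all 576 among them. The count was 168 without Negative replicate 2, 205 without Negative replicate 3, and 216, 237 and 259 without BPA replicate 1, 2 or 3. Of 42 called genes of the naming rule, 26 lost the call without some single library, and 16 kept it: CLEC3A, DHRS3, EPAS1, ERBB2, GPER1, GREB1, IL1R1, MYB, NTN4, PGR, PKIB, RFC4, SFXN2, TGFBI, TPD52L1 and UPK2.

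BPAF against Negative put the same question to bisphenol AF. BPAF raised 406 genes and lowered 402, 808 in all, with 204 of them differing at least 2-fold. PGR rose 8.29-fold (log2 3.05 ± 0.45, adjusted p = 0.00377) and GREB1 4.64-fold (log2 2.21 ± 0.29, adjusted p = 0.00241), and the log2 value of GREB1 was 6.32 ± 0.34. PKIB (2.11), STC1 (2.10), NPY1R (2.09), RET (2.01), SFXN2 (1.97), MSMB (1.93), RERG (1.90) and MYB (1.77) made up the rest of the 10 largest named rises. CLEC3A fell 5.42-fold (log2 -2.44 ± 0.33, adjusted p = 0.00274) and EPAS1 5.17-fold (log2 -2.37 ± 0.28, adjusted p = 0.00144). ALDH1A3 (-2.28), PSCA (-2.21), DHRS3 (-1.88), UPK2 (-1.71), the serine protease TMPRSS2 (-1.67), NTN4 (-1.65), KRT81 (-1.63) and GRHL3 (-1.59) fell. CXCL12 rose (1.38 ± 0.35, adjusted p = 0.0422), while TFF1 had 1.49 ± 0.54, adjusted p = 0.143, or 0.000136 with the replicate block, and PDZK1 1.60 ± 0.46, adjusted p = 0.0688, or 0.00283 with the block. MYC (0.34 ± 0.19, adjusted p = 0.361), CCND1 (0.18 ± 0.11, adjusted p = 0.414) and ESR1 (0.07 ± 0.15, adjusted p = 0.861) did not pass.

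Of 42 estrogen-induced genes 16 rose with BPAF, 26 adjusted over the list alone and 31 with the replicate block (median 1.08, adjusted p = 1.34e-19, and adjusted p = 0.0529 with an estimated correlation), among them TPD52L1 (1.01) and STC2 (1.28). Of 16 estrogen-repressed genes 6 fell, 7 adjusted over the list alone and 12 with the block, IL1R1 (-2.00) and PIK3IP1 (-0.75) among them (median -0.72, adjusted p = 4.75e-07, and adjusted p = 0.0529 with an estimated correlation). Rises were found in 13 of 34 DNA replication genes, 33 adjusted over the list alone and 34 with the block (median 0.70, adjusted p = 2.20e-21, and adjusted p = 0.215 with an estimated correlation). They were found in 11 of 32 mitosis genes, 29 adjusted over the list alone and 30 with the block (median 0.70, adjusted p = 2.67e-18, and adjusted p = 0.230 with an estimated correlation). HIST1H2AB (0.92), HIST1H3G (0.83) and HIST1H4D (0.71) rose of 25 histone genes, 15 adjusted over the list alone and 18 with the block (median 0.56, adjusted p = 9.01e-11, and adjusted p = 0.281 with an estimated correlation). UTP20 (0.41), NOP58 (0.52) and POLR1B (0.31) rose of 18 ribosome biogenesis genes, 12 adjusted over the list alone and 10 with the block (median 0.34, adjusted p = 1.28e-06, and adjusted p = 0.215 with an estimated correlation). JUNB (-0.92), JUN (-0.69) and IER2 (-0.43) fell of 10 immediate early genes, 3 adjusted over the list alone and 6 with the block (median -0.56, adjusted p = 0.00366, and adjusted p = 0.394 with an estimated correlation).

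All 14 interferon-stimulated genes had values below 0 with BPAF (median -0.77, adjusted p = 0.00125, and adjusted p = 0.497 with an estimated correlation), such as MX1 (-1.14 ± 0.55, adjusted p = 0.288) and IFI6 (-1.06 ± 0.42, adjusted p = 0.189, 0.00404 with the replicate block). By limma 0 of them passed, and 2 with the block. The cholesterol list was called higher (median 0.32, adjusted p = 0.0281, and adjusted p = 0.709 with an estimated correlation), where FADS1 rose (0.63), and 11 of 21 genes rose with the block. Among lists that were not called, TIPARP rose (0.72) and AHRR fell (-1.26) of the aryl hydrocarbon receptor targets (list adjusted p = 0.675), HSP90B1 rose (0.40) in the unfolded protein response (0.851), and SESN2 fell (-0.46) among p53 targets (0.205). EGLN3 (-1.52) and VEGFA (-0.50) fell among hypoxia genes (0.287), and in the list of nuclear receptors, GPER1 and AHR (0.205) PGR and GPER1 (0.67) rose and RARG (-0.45) and PPARG (-0.96) fell. No member passed limma's adjusted test among PXR and CAR targets (list adjusted p = 0.205), NRF2 targets (0.555), heat shock genes (0.482) or luminal markers (0.482). Adjusted over the list alone, ABCC3, XBP1, CHAC1, HSPA8, HSPD1, HSPE1 and AHR passed besides the members just given, AHR being named after its value was seen.

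With the replicate block 3597 genes changed with BPAF, all 808 among them, and 2674 with the block and without BPAF replicate 2. The count was 247 without Negative replicate 2, 282 without Negative replicate 3, 376 without BPAF replicate 1 and 336 without BPAF replicate 2. The planned fit takes its spread from all groups, and pairs of BPAF libraries differed most, with a chi-square per gene of 53.9 to 64.0. A fit on the 6 libraries of this comparison alone called far fewer genes, as given below. The interferon list had an adjusted p = 0.0741 without BPAF replicate 2, and the cholesterol list 0.651 without BPAF replicate 2 and 0.435 without Negative replicate 3. Of 54 genes of the rule called for BPAF, 35 lost the call without some single library, and 19 kept it: CLEC3A, DHRS3, EPAS1, ERBB2, GINS1, GREB1, IL1R1, MYB, NTN4, PGR, PKIB, RFC4, SFXN2, STC1, STC2, TIPARP, TMPRSS2, TPD52L1 and UPK2.

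**Figure D3:**
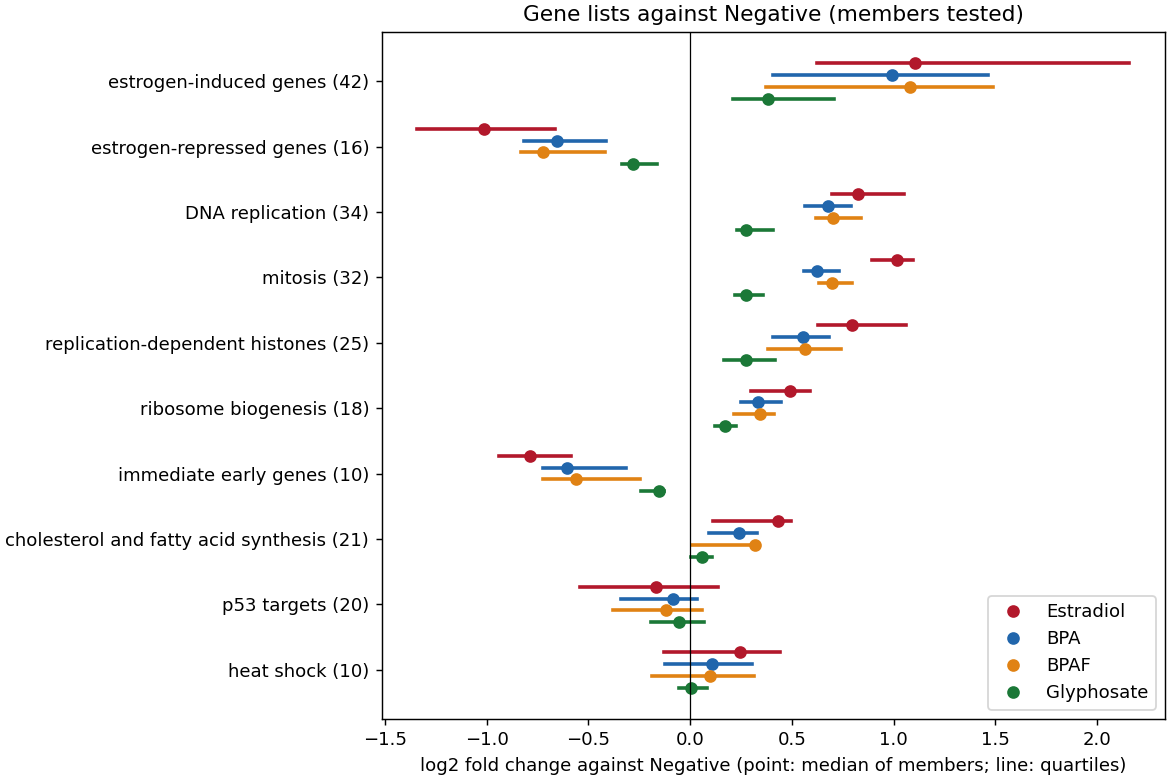
Log2 fold changes against Negative (x axis) of the members of 10 gene lists (y axis) for Estradiol, BPA, BPAF and Glyphosate. Points are medians of the members and lines their quartiles, and the median of the estrogen-induced genes was 1.11, 0.99, 1.08 and 0.38 in that order.

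Glyphosate against Negative asked whether the herbicide alters expression in these cells. GREB1 had the smallest p of the genes above the median level, with a log2 change of 1.59 ± 0.29, adjusted p = 0.777, 0.106 with the replicate block. Next came AMZ1 (0.78), the protocadherin PCDH1 (-0.45), RN7SL809P, a copy of the 7SL RNA that the rule's name filter did not catch (0.97), and NECTIN4, a cell adhesion protein (-0.44). PGR had 1.41 ± 0.45, adjusted p = 1.00, TFF1 0.93 ± 0.54, adjusted p = 1.00 and CXCL12 0.85 ± 0.35, adjusted p = 1.00, and the values of MYC (0.39), PDZK1 (0.52), CCND1 (0.07) and ESR1 (0.21) did not pass either. By limma 0 genes changed, with 639 at an unadjusted p under 0.05, where chance gives 949, and a smallest adjusted p of 0.144. Without a replicate term the differences between experiments stay in the spread, so a count under 949 does not mean less than chance. The replicate block gave 0 genes as well, with 1946 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0861. Voom on recovered counts, added after the data were seen, gave 0 genes, and voom with the block gave 194, of which 71 were higher and 123 lower. TFF1 (adjusted p = 0.00478), GREB1 (0.00549) and PGR (0.00627) were among these 194, and CXCL12, MYC, PDZK1, CCND1 and ESR1 were not. In that fit, which shares the Negative libraries, 192 of the 194 also changed with estradiol in the same direction and 1 in the opposite direction.

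As a list, the estrogen-induced genes were higher with glyphosate (median 0.38, adjusted p = 1.12e-15, and adjusted p = 0.185 with an estimated correlation), and 41 of 42 had values above 0, SERPINA1 being below. GREB1, MYB (0.85), STC2 (0.77), TPD52L1 (0.49) and KRT13 (1.82) passed adjusted over the list alone, 5 genes against 22 with the replicate block, and KRT13 and SERPINA1 were named after their values were seen. The estrogen-repressed genes were lower (median -0.28, adjusted p = 0.00105, and adjusted p = 0.259 with an estimated correlation), and IL1R1 (-0.89) passed adjusted over the list alone. All 34 DNA replication genes had values above 0 (median 0.27, adjusted p = 3.71e-14, and adjusted p = 0.454 with an estimated correlation), and RFC4 (0.49) passed adjusted over the list alone. All 32 mitosis genes did too, TTK (0.39) and KIF11 (0.40) among them (median 0.28, adjusted p = 6.70e-10, and adjusted p = 0.490 with an estimated correlation). The histones, with HIST1H2AB at 0.53 (median 0.27, adjusted p = 1.45e-08, and adjusted p = 0.479 with an estimated correlation), and ribosome biogenesis, with POLR1B at 0.21 (median 0.17, adjusted p = 1.69e-06, and adjusted p = 0.259 with an estimated correlation), were higher. Ribosome biogenesis was also called with the replicate block and an estimated correlation, here as for estradiol, BPA and BPAF against Negative.

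The immediate early genes, with JUNB at -0.41, had an adjusted p = 0.136 for glyphosate, 0.0244 with the replicate block and adjusted p = 0.276 with the block and an estimated correlation. Interferon-stimulated genes had an adjusted p = 0.0504 (median -0.27) and the cholesterol list 0.471. The other lists did not pass: aryl hydrocarbon receptor targets (0.986), PXR and CAR targets (0.941), NRF2 targets (0.941), the unfolded protein response (0.182), heat shock (0.965), p53 targets (0.601), hypoxia (0.449), nuclear receptors (0.986) and luminal markers (0.594). Without Negative replicate 1, 3 genes changed: GREB1 (1.99), STC2 (1.05) and AMZ1 (1.02). Without Negative replicate 3 the mitosis list had an adjusted p = 0.335.

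BPAF against BPA compared 2 structural relatives: BPAF carries trifluoromethyl groups where BPA has methyl groups on the carbon between its phenol rings. Their doses are not given, so the difference of the responses cannot be read at matched dose. By limma 0 genes differed, with 345 at an unadjusted p under 0.05 where chance gives 949, and a smallest adjusted p of 1.000. This fit too leaves the differences between experiments in the spread, which can lower the count. With the replicate block 0 genes differed, with 721 at an unadjusted p under 0.05 and a smallest adjusted p of 0.645, and voom gave 0 with and without the block. Since 721 is also under 949, the differences between experiments do not account for the whole shortfall. The cause of the rest was not tested, and neither count is read as less than chance. The difference in PGR was 0.00 with a 95% interval of -0.98 to 0.98 (-0.55 to 0.55 with the replicate block), that in GREB1 -0.23 with -0.84 to 0.38 (-0.87 to 0.41), that in TFF1 -0.31 with -1.46 to 0.85 (-0.66 to 0.04), that in CXCL12 0.00 with -0.75 to 0.75 (-0.50 to 0.50), that in PDZK1 0.24 with -0.75 to 1.23 (-0.39 to 0.88), that in MYC -0.02 with -0.43 to 0.38 (-0.32 to 0.28), that in CCND1 0.01 with -0.22 to 0.24 (-0.18 to 0.20) and that in ESR1 -0.13 with -0.45 to 0.18 (-0.27 to 0.01). TFF1 and ESR1 were lower with BPAF in 3 of 3 pairs of the same number, at unadjusted p = 0.0795 and 0.0594 with the block. Neither passed, at limma's adjusted p = 0.999 with the block for both. Over all genes the median half-width of the 95% interval was 0.48, or 0.34 with the replicate block. For 72.0% of genes the interval lay within a log2 difference of 1 on either side, and for 49.5% within 1.5-fold. Differences inside these bounds are not excluded. Among named genes above the median level the smallest p were those of TMEM128 (-0.42), TMEM140 (0.47), SIL1 (-0.33), METTL23 (-0.30) and GPR89B (0.28).

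The median difference between BPAF and BPA was 0.01 for the 42 estrogen-induced genes (adjusted p = 0.861) and -0.03 for the 16 estrogen-repressed genes (adjusted p = 0.959). The 14 interferon-stimulated genes were all below 0, with IFIT3 at -1.84 ± 1.43, which had an SD of 3.72 with BPAF and paired differences from -5.06 to 1.28, and IFI6 at -0.50 ± 0.42, and were called lower with BPAF (median -0.29, adjusted p = 0.0174, and adjusted p = 0.966 with an estimated correlation). That call was lost without BPAF replicate 2 (adjusted p = 0.894) and without BPA replicate 3 (0.849), and with the replicate block and without BPAF replicate 2 (0.440). DNA replication had an adjusted p = 0.553, mitosis 0.374, and the other 13 lists had 0.959.

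BPA against Estradiol and BPAF against Estradiol asked where the bisphenols differ from the hormone, again at doses that are not given. Of 18971 genes 12 differed for BPA and 13 for BPAF. CLEC3A was higher with BPA (2.09 ± 0.33, adjusted p = 0.0473) and with BPAF (2.08 ± 0.33, adjusted p = 0.0494) than with estradiol, and its mean log2 values were 4.17 in Negative, -0.34 with estradiol, 1.75 with BPA and 1.73 with BPAF. LIMA1, an actin-binding protein (0.87 ± 0.14, adjusted p = 0.0473 for BPA and 0.88 for BPAF), SALL4, a transcription factor (0.85 and 0.90), CCDC159 (0.85 and 0.84), FAM171B (0.80 and 0.80) and ERC2 (1.43 and 1.44) were higher with both bisphenols. LGALS1, galectin 1 (-0.83 and -0.81), and the transcription factor TFAP2C (-0.57 and -0.55) were lower with both. GRM4, a glutamate receptor (0.69), and PCDH1 (0.62) were called higher for BPA only. Their mean log2 values with estradiol, BPA and BPAF were 1.57, 2.26 and 2.24 for GRM4 and 2.58, 3.20 and 3.06 for PCDH1. The keratin KRT15 (1.34 ± 0.19, adjusted p = 0.0366) and the homeobox gene MSX2 (0.69) were called higher and DOK7 (-1.09) lower for BPAF only. Their means with estradiol, BPA and BPAF were 1.785, 2.78 and 3.12 for KRT15, 2.73, 3.21 and 3.43 for MSX2 and 4.88, 4.01 and 3.79 for DOK7. A call for a single bisphenol thus does not set it apart from the other, and no gene was called in BPAF against BPA. The remaining called genes were the pseudogenes AC010442.1, for both, and AMMECR1LP1, for BPAF, and the antisense gene AC091544.7, for BPA. ERC2 and these 3 were named after their values were seen.

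Among genes fixed for their response to estrogen, GREB1 was -1.21 ± 0.29, adjusted p = 0.239 for BPA and -1.45 ± 0.29, adjusted p = 0.10, for BPAF (0.0276 with the replicate block), TFF1 -1.39 ± 0.54, adjusted p = 0.648 for BPA (0.00174 with the block) and -1.69 ± 0.54, adjusted p = 0.435 for BPAF (0.000515 with the block), and CXCL12 -1.26 and -1.25 (adjusted p = 0.346 and 0.345, 0.0188 and 0.0163 with the block). PGR (-0.64 and -0.63), PDZK1 (-0.12 and 0.12), MYC (-0.05 and -0.08), CCND1 (-0.22 and -0.21) and ESR1 (0.23 and 0.10) did not pass in either comparison or with the block. The estrogen-induced genes were lower than with estradiol, with medians of -0.32 for BPA (adjusted p = 9.68e-09, and adjusted p = 0.399 with an estimated correlation) and -0.35 for BPAF (adjusted p = 1.83e-06, and adjusted p = 0.608 with an estimated correlation). Over all genes 0 of the list passed limma's adjusted test in either comparison. Adjusted over the list alone 5 were lower for BPA (GREB1, CXCL12, MYBL1, EGR3 and FKBP4), and 8 lower and 4 higher for BPAF, the higher ones being KRT13 and, named after their values were seen, STC2, AGR2 and HSPB8. The block gave 7 lower and 1 higher for BPA, and 10 lower and 3 higher for BPAF. KRT13, a keratin, had mean log2 values of 0.86 with estradiol and 3.06 with BPAF (2.20 ± 0.55, adjusted p = 0.269, 0.00200 with the block). The estrogen-repressed genes were higher, at 0.42 (adjusted p = 8.99e-06, and adjusted p = 0.190 with an estimated correlation) and 0.31 (adjusted p = 0.000145, and adjusted p = 0.372 with an estimated correlation), and IL1R1 passed in both when adjusted over the list alone.

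Mitosis genes were lower with the bisphenols than with estradiol, at -0.32 for BPA (adjusted p = 2.89e-11, and adjusted p = 0.568 with an estimated correlation) and -0.27 for BPAF (adjusted p = 4.33e-07, and adjusted p = 0.608 with an estimated correlation). DNA replication was at -0.16 (adjusted p = 2.06e-05, and adjusted p = 0.643 with an estimated correlation) and -0.13 (adjusted p = 0.00336, and adjusted p = 0.733 with an estimated correlation). The histones were at -0.29 (adjusted p = 2.37e-08, and adjusted p = 0.568 with an estimated correlation) and -0.32 (adjusted p = 5.89e-07, and adjusted p = 0.608 with an estimated correlation). Ribosome biogenesis was at -0.09 (adjusted p = 0.00270, and adjusted p = 0.568 with an estimated correlation) and -0.11 (adjusted p = 0.00405, and adjusted p = 0.608 with an estimated correlation). In these 4 lists 0 members passed limma's adjusted test. With the replicate block 5 more lists passed in both comparisons, with adjusted p for BPA and BPAF of 0.0162 and 0.00542 for aryl hydrocarbon receptor targets, 0.0151 and 0.0143 for heat shock, 0.000158 and 0.00174 for cholesterol, 0.0151 and 0.0175 for hypoxia and 0.0171 and 0.0143 for immediate early genes. Without the block these had 0.401 and 0.225, 0.124 and 0.137, 0.0820 and 0.210, 0.165 and 0.190, and 0.124 and 0.0911. None of the 5 passed with the block and an estimated correlation, at adjusted p = 0.304 and 0.284, 0.305 and 0.329, 0.223 and 0.308, 0.195 and 0.279, and 0.195 and 0.279 in the same order. The adjusted p of the other lists was 0.165 and 0.199 for PXR and CAR targets, 0.928 and 0.726 for NRF2 targets, 0.928 and 0.964 for the unfolded protein response, 0.928 and 0.726 for p53 targets, 0.174 and 0.518 for interferon-stimulated genes, 0.928 and 0.826 for nuclear receptors and 0.374 and 0.225 for luminal markers.

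With the replicate block 426 genes differed for BPA and 521 for BPAF against estradiol, all of the 12 and 13 among them, and voom without the block gave 0 and 17. Each named call was lost without some single library: for BPA the count was 2 without Estradiol replicate 1, 1 without Estradiol replicate 3, 1 without BPA replicate 3 and 0 without each other library, and for BPAF it was 3 without BPAF replicate 3, 2 without BPAF replicate 2, 2 without Estradiol replicate 3 and 0 without each other library. Ribosome biogenesis had an adjusted p = 0.120 without BPA replicate 3 and 0.0759 without Estradiol replicate 1 for BPA, and 0.176 without BPAF replicate 3 and 0.101 without Estradiol replicate 1 for BPAF. DNA replication had 0.181 and 0.140 without the same libraries for BPAF.

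**Figure D4:**
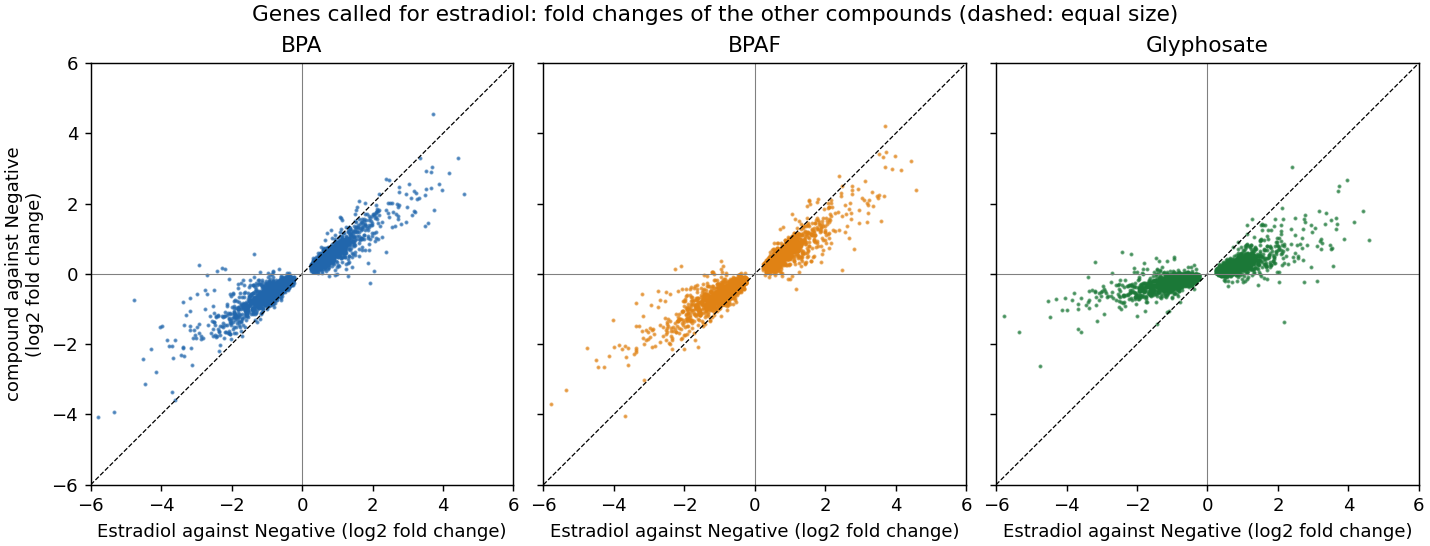
Log2 fold changes of the 2696 genes that changed with estradiol, with Estradiol against Negative on the x axis and BPA, BPAF or Glyphosate against Negative on the y axis. Each point is a gene, the line marks equal change, and the share of genes that changed less than with estradiol was lowest for BPAF, at 94.1%, and highest for Glyphosate, at 99.7%.

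Fold changes against Negative were compared between the compounds across 18971 genes, which are not independent replicates, in 6 pairs. The correlation was 0.754 for Estradiol and BPA, 0.745 for Estradiol and BPAF, 0.549 for Estradiol and Glyphosate, 0.754 for BPA and BPAF, 0.592 for BPA and Glyphosate and 0.584 for BPAF and Glyphosate. Since all pairs share the Negative libraries, simulated groups with no change gave a mean of 0.502 and a range of 0.473 to 0.534 over 100 simulations. With no library shared between the 2 fold changes the median correlations were 0.373, 0.382, 0.176, 0.341, 0.152 and 0.152 in the same order. Of the genes called, 286 were higher and 269 lower with both estradiol and BPA, where lists drawn independently give 20.8 and 20.1. For estradiol and BPAF 371 were higher and 370 lower, against 28.5 and 28.9, and for BPA and BPAF 248 and 239, against 6.33 and 5.93, and 0 genes were called in opposite directions in these 3 pairs. Unchanged groups simulated against shared Negative libraries gave 0 to 1 shared calls per direction. Neither reference holds both the effects and the shared libraries. Part of the excess may come from the shared libraries. The covariance of fold changes was 0.242, 0.248, 0.126, 0.196, 0.106 and 0.108 in the order of the correlations, against 0.0559 with no change. Of the 2696 genes called for estradiol, 99.4% had the same sign with BPA, 99.2% with BPAF and 95.1% with Glyphosate in fold changes that share the Negative libraries. Simulated unchanged groups gave 84.5%, 84.4% and 84.4% among as many genes of smallest p. These genes were picked for a large change with estradiol, which makes a smaller change in another group more frequent.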

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

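Voom on the recovered counts, with and without the replicate block, the removal of all replicate 3 libraries, the removal of BPAF replicate 2 with the block the block with an estimated correlation and the simulated correlations below were tests chosen after the data were seen; the other settings were fixed beforehand. In the 7 comparisons, the counts of genes stayed within 1.5 times under median-centred scaling, and for Estradiol against Negative (2696) also with no filter, the stricter filter, the higher floor, quantile scaling, no trend, the fold minimum, voom and all replicate 3 libraries left out. With the replicate block the counts were 5672 for Estradiol, 3287 for BPA and 3597 for BPAF against Negative, and 426 for BPA and 521 for BPAF against Estradiol, with all genes called without the block among them, and the block ended no call of a named gene. Voom with the block gave 5908, 3805 and 4222 genes for the first 3, 194 for Glyphosate, and 696 and 851 for the last 2, and voom alone gave 0 for BPA against Estradiol. Fitting the 6 libraries of a comparison alone, so with fewer samples, gave 1557, 98 and 25 genes for the first 3 and 0 and 0 for the last 2. The count for BPAF fell below that for BPA, from 808 and 576, so the number of samples does not alone account for the drop. Pairs of BPAF libraries had the largest chi-square per gene, 53.9 to 64.0 against 11.6 to 52.8 in the other groups. The planned fit takes its spread from all groups. With no filter, and so more genes tested, the counts were 283 for BPA, 425 for BPAF and 1 (RN7SL277P) for Glyphosate against Negative, and 0 and 0 against Estradiol. Without a trend they were 1 (RN7SL277P) for Glyphosate and 0 and 0 against Estradiol. A floor 10 times higher gave 4 and 5 against Estradiol, quantile normalization 1 for BPA against Estradiol, the stricter filter 25 for BPAF against Estradiol and the fold minimum of 1.5 gave 529 for BPAF against Negative. Without all replicate 3 libraries, so with fewer samples, they were 209 for BPA and 333 for BPAF against Negative, and 1 and 3 against Estradiol. With the block and without BPAF replicate 2 they were 2674 for BPAF against Negative and 294 against Estradiol. The block takes the differences shared by libraries of the same number out of the spread. In BPAF against BPA it narrowed the median half-width of the 95% interval from 0.48 to 0.34. The cause was not otherwise tested for the changes with the block, the trend, the floor, quantile scaling, the stricter filter or voom. In BPAF against BPA 0 genes passed under each of these settings and without each library in turn.

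Leaving out each library in turn gave 1577 to 2591 genes for Estradiol, 168 to 771 for BPA, 247 to 934 for BPAF and 0 to 3 for Glyphosate against Negative, and 0 to 2 for BPA and 0 to 3 for BPAF against Estradiol. The highest counts were without Estradiol replicate 3 for Estradiol, Negative replicate 1 for BPA, BPAF and Glyphosate, and Estradiol replicate 1 and BPAF replicate 3 for BPA and BPAF against Estradiol, and the lowest without Estradiol replicate 2 for Estradiol and Negative replicate 2 for BPA and BPAF. The number of lists called was 9, 7, 9, 6, 1, 6 and 6 in the 7 comparisons. It was 0 in each with an estimated correlation, and with the block and an estimated correlation 1 (ribosome biogenesis) for each of the 4 comparisons with Negative and 0 for the other 3. With the block it was 11 for BPA and 11 for BPAF against Estradiol, and with the block and without BPAF replicate 2 it was 0 for BPAF against BPA and 10 for BPAF against Estradiol. Without single libraries it was 0 to 3 for BPAF against BPA and 4 to 10 for BPAF against Estradiol. The cause was not tested for the list calls lost or gained. The correlations of fold changes were higher with the stricter filter, which leaves out genes with few reads, at 0.896 (Estradiol and BPA), 0.887 (Estradiol and BPAF), 0.720 (Estradiol and Glyphosate), 0.923 (BPA and BPAF), 0.765 (BPA and Glyphosate) and 0.772 (BPAF and Glyphosate). Without single Negative libraries they ran from 0.760 to 0.803, 0.752 to 0.794, 0.564 to 0.653, 0.769 to 0.806, 0.631 to 0.698 and 0.623 to 0.681 in that order. Unchanged groups that share the Negative libraries, simulated with the effects of the experiments, gave a mean of 0.494 (0.384 to 0.569) with the stricter filter, and 0.629 (0.603 to 0.649), 0.644 (0.623 to 0.669) and 0.659 (0.640 to 0.680) without Negative replicate 1, 2 and 3. All 6 pairs lay above this with the stricter filter. Without Negative replicate 2 or 3 no pair with Glyphosate lay above it, and the other 3 pairs lay above it without each. The simulated groups hold no effect of a compound, and effects that are not shared lower a correlation. Without Negative replicate 3, Estradiol and Glyphosate lay under the lowest simulated value, at 0.564 against 0.640. These 2 settings therefore do not decide on an agreement of Glyphosate with another compound. The median of the estrogen-induced genes without single libraries ran from 0.75 to 1.14 for BPA, 0.82 to 1.17 for BPAF and 0.33 to 0.52 for Glyphosate, and without all replicate 3 libraries it was 0.90 for BPAF.

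None of the called genes of the naming rule that were run in these settings, 72, 42 and 54 against Negative and 9 and 10 against Estradiol, changed direction; genes named outside the rule were not run. Among the fixed genes of the rule, where they were not called, the log2 change turned sign in 39 values, and the cause was not tested. In BPAF against BPA, CXCL12 was -0.00885 with the higher floor, -0.0199 with voom and -0.0501 with voom and the block, and it ran from -0.27 to 0.35 without single libraries. PGR was -0.00270 with quantile normalization and CCND1 -0.00405. With the block and without BPAF replicate 2, PGR was -0.18, CCND1 -0.0849 and PDZK1 -0.0229. Without single libraries PGR ran from -0.18 to 0.27, CCND1 from -0.0719 to 0.0576, PDZK1 from -0.0691 to 0.73, MYC from -0.15 to 0.15 and TFF1 from -0.68 to 0.10, and MYC was 0.0271 without all replicate 3 libraries. In BPA against Estradiol, MYC ran from -0.23 to 0.0767 and PDZK1 from -0.47 to 0.20 without single libraries. In BPAF against Estradiol, MYC ran from -0.20 to 0.0552 and PDZK1 from -0.23 to 0.60, and PDZK1 was -0.15 with the block and without BPAF replicate 2. ESR1 ran from -0.19 to 0.0668 in Estradiol against Negative and from -0.0883 to 0.16 in BPAF against Negative, where it was -0.0214 without all replicate 3 libraries. CCND1 ran from -0.00457 to 0.15 in Glyphosate against Negative. Over all settings, 49 of 72 named calls for Estradiol, 11 of 42 for BPA and 6 of 54 for BPAF against Negative were never lost. Depth limits the genes with few reads most.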

Other observations

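The tests of the experiments, of the Glyphosate pattern, of the shared deviations and of the mitochondrial copies were chosen after the results were seen, and those of other splits of the libraries before. Between the experiments that the replicate numbers mark, the groups differed together. Replicates 3 differed from replicates 1 and 2 in 6410 genes, 2773 higher and 3637 lower, with the group as a term. FN1, fibronectin (2.13), CDKN2B, a cell cycle inhibitor (2.23), PMEPA1 (1.83) and the actin-associated PALLD (1.81) were higher in replicates 3. The sodium channel subunit SCNN1A (-2.60), the adhesion proteins CEACAM6 (-2.09) and CEACAM5 (-1.86) and the mucin MUC1 (-1.97) were lower. Of 21 genes of cholesterol and fatty acid synthesis 20 were lower (median -0.51, adjusted p = 5.07e-12, and adjusted p = 0.149 with an estimated correlation), as were 26 of 34 DNA replication genes (adjusted p = 3.13e-07, and adjusted p = 0.613 with an estimated correlation) and 22 of 32 mitosis genes (adjusted p = 2.81e-06, and adjusted p = 0.613 with an estimated correlation). Of 42 estrogen-induced genes 19 were lower and 5 higher (median -0.26, adjusted p = 0.0128, and adjusted p = 0.613 with an estimated correlation), and 7 of 10 immediate early genes were higher (adjusted p = 0.000337, and adjusted p = 0.149 with an estimated correlation). Histones (adjusted p = 0.00304, and adjusted p = 0.613 with an estimated correlation), ribosome biogenesis (adjusted p = 0.0263, and adjusted p = 0.194 with an estimated correlation) and luminal markers (adjusted p = 0.0476, and adjusted p = 0.613 with an estimated correlation) were called lower as lists. The median of the luminal markers was -0.11, and it was lower in 3 of 5 groups only, against 5 of 5 for the other lists called here.

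Replicates 2 differed from replicates 1 in 1649 genes, 823 higher and 826 lower. CYP1A1 (2.94) and CYP1B1 (1.28), enzymes induced through the aryl hydrocarbon receptor, were higher, and 5 of 6 targets of that receptor were (median 1.06, adjusted p = 3.45e-09, and adjusted p = 0.0633 with an estimated correlation). AKR1C2 (1.29) was higher too, and 8 of 12 NRF2 oxidative stress targets were (median 0.77, adjusted p = 2.77e-11, and adjusted p = 0.0633 with an estimated correlation). GDF15, a secreted stress cytokine (1.43), was higher, with 8 of 20 p53 targets (adjusted p = 6.85e-07, and adjusted p = 0.186 with an estimated correlation) and 12 of 21 cholesterol genes (adjusted p = 2.77e-11, and adjusted p = 0.0633 with an estimated correlation). Lower were 9 of 34 DNA replication genes (adjusted p = 3.45e-09, and adjusted p = 0.300 with an estimated correlation), 6 of 32 mitosis genes (adjusted p = 4.01e-06, and adjusted p = 0.378 with an estimated correlation) and 9 of 25 histone genes (adjusted p = 7.30e-07, and adjusted p = 0.300 with an estimated correlation). PXR and CAR targets (adjusted p = 0.00120, and adjusted p = 0.0633 with an estimated correlation), heat shock (adjusted p = 0.00817, and adjusted p = 0.300 with an estimated correlation) and hypoxia (adjusted p = 0.0158, and adjusted p = 0.186 with an estimated correlation) were called higher as lists, and ribosome biogenesis (adjusted p = 0.00473, and adjusted p = 0.0633 with an estimated correlation) and interferon-stimulated genes (adjusted p = 6.83e-05, and adjusted p = 0.300 with an estimated correlation) lower. The median of the interferon-stimulated list was lower in 4 of 5 groups. The interferon-stimulated IFI27 (-0.94) and IFITM3 (-0.96), named after their values were seen like the other genes of these paragraphs, were lower. Larger falls were those of MTRNR2L6 (-2.86), MTRNR2L1 (-2.82), MTRNR2L8 (-2.76) and MTRNR2L12 (-2.63), nuclear copies of a mitochondrial ribosomal RNA, each in the same direction in 4 groups.

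Genes that respond to estradiol lay on the estradiol side of Negative in the Glyphosate libraries, although 0 single genes passed limma's test with or without the replicate block. Voom with the block called 194 genes, of which 192 also changed with estradiol in the same direction, in fold changes that share the Negative libraries. Sharing of the Negative libraries was tested by choosing genes on 2 experiments and reading the sign in the third. Of 3700, 3768 and 3658 genes, 83.5%, 81.9% and 80.4% had the estradiol sign in Glyphosate, which argues against errors of shared libraries as the whole cause. A difference of the Negative group that recurs in every experiment would pass this test and was not tested. Depth was tested on 36 estrogen-induced genes with at least 200 counts, whose medians were 0.321, 0.449 and 0.446 in experiments 1, 2 and 3, of which 1 and 2 had similar depths in both groups, and this argues against depth and the floor. A weak estrogenic activity of glyphosate may account for the pattern, and so could an estrogenic source other than the compound, such as estrogen carried over from a neighbouring well. These cannot be told apart: the slope of the Glyphosate on the Estradiol change was 0.312 over the estrogen-induced list, and there was no dose series or receptor blocker to separate them.

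Libraries with the same replicate number shared deviations from their group means in every group. Counting noise and depth were tested on 9951 genes with at least 200 counts and without the deepest and the shallowest library, and the median correlation of 22 pairs was 0.623 (0.339 to 0.852), which argues against them. A bias by gene length or abundance was tested by taking the mean of each of 400 bins of exon length and level from the deviations, which removed 9.66% of their variance where chance gives 4.01%, and the median correlation was 0.612 (0.322 to 0.841), which argues against such a bias as the whole cause. Conditions of the cells that changed between experiments, such as medium or culture age, may underlie these shifts, and so may the preparation of the libraries. The deposited columns are numbered in the order of the replicates, so these cannot be told apart. No condition of either kind is recorded that could test it.

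Nuclear copies of mitochondrial genes were among the highest values, with MTCO1P12 at a mean log2 of 12.29, while all 37 genes of the mitochondrial genome were at zero. For 12 of 13 mitochondrial mRNAs the copy most like the gene was also the highest of its copies, where chance gives 0.951 if the mRNAs are independent. They are not. Each of the 12 copies lies in the same stretch of chromosome 1 (629062 to 634922) or of chromosome 5 (134923303 to 134928326). The chance value is therefore no measure of the evidence. Mitochondrial reads placed on these nuclear stretches may account for the pattern. A first test, by a limit of 97% identity, gave 7 copies with a lowest log2 of 8.25 and did not part the high copies from the rest, since MTND4P12, at 95.8% identity, had 9.44, and Spearman's rho of identity and level over 350 copies was 0.0796. No biological explanation was tested.

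The 6 libraries of a comparison can be split in 10 ways, which cannot give a share under 0.05. As many genes as the real split were called in 1 of 10 splits for Estradiol against Negative (2696), BPA against Negative (576), BPAF against Negative (808), BPA against Estradiol (12) and BPAF against Estradiol (13), with 0 genes in the highest other split of each. For Glyphosate against Negative and BPAF against BPA the real split gave 0 genes and so did all the others, 10 of 10. Among the splits that part all 3 pairs of the same replicate number the highest other count was also 0. Each other split puts libraries of both groups on each side, so an effect of a compound goes into the spread. Where there is such an effect, a count of 0 was close to fixed in advance and does not weigh on chance. The real count for estradiol with the replicate block was 5672, and the other splits were not run with the block.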
